A study of Arabidopsis thaliana with 12 samples.

How the data were processed

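Total RNA from wild-type Arabidopsis thaliana cell culture of the Columbia-0 ecotype was measured on 12 arrays, 6 of water-treated and 6 of cytokinin-treated culture. Per the labels, cytokinin was given for 2 h. One label calls the control water-treated and another calls it untreated, and no duration is given for it; it is called water here, and whether it had a mock treatment of the same length is not known. Which cytokinin, which array and which scanner were used is not given in the sources used here. Both groups carry the replicate numbers 1 to 6, and the labels do not say whether the replicates are separate cultures, so p-values measure the spread between these samples, which may be technical.

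The deposited values are hybridization intensities on a linear scale, 1 table of 3439 features by 12 arrays. How the authors scaled them or corrected background is not given in the sources used here. No value is below 0, between 155 and 172 features per array are listed at exactly 0, and the highest value lies just under 100. That same value was listed for 1 or 2 features on every cytokinin array, and for 1 on water arrays 3 and 4 only. Whether it is a ceiling is not given, and changes of features that reach it may be shown as too small. The total intensity per array ran from 3743 to 3875, and the median log2 intensity of the arrays spanned 0.141. The number of arrays limits the precision.

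Gene names came from the platform annotation, updated through gene identifiers in a RefSeq gene table of assembly TAIR10.1, used for names only. Of the features, 692 have 1 gene name, 870 have several and 1877 are unnamed here. The RefSeq table held 690 of the 692. Only features with 1 gene name are given as genes, and no coordinates are printed because the sources name no build.

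The arrays were quantile-normalized, since their medians differed by over 0.1 on the log2 scale. That difference lay between the groups: medians ran from -0.466 to -0.427 in water and from -0.569 to -0.528 in cytokinin. The normalization therefore also removed a shift between the groups. Over the features tested, the median log2 change was -0.072 on the values as deposited and 0.003 after it. Values were floored at the pooled 10th percentile of positive values (0.258) and log2-transformed. The 348 features at the floor on all arrays were left out, 125 of them listed at 0 on every array, and 3091 were tested, 613 with 1 gene name. The choices made before the data were examined set no filter on dim features, so this omission departs from them. With the 348 kept, the count of changed features given below is 63 and not 48. Cytokinin and water were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 changes are cytokinin minus water, and intensities printed as means are the normalized ones before the floor. Plots were drawn with matplotlib 3.10.9.

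The following choices were made before the data were examined: the 2-group fit without a block, the named-gene rule, 24 gene lists and 25 of the other settings. The rule names each type-A response regulator, the 12 largest rises and 12 largest falls past the threshold among features with 1 gene name (all where fewer pass), and up to 4 members of each list. None of the 345 list genes is the only gene of a feature, and 4 occur on features with several genes. The type-A response regulator mean and the tests of these lists, cytosolic ribosomal proteins included, were therefore not run.

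Choices made after seeing the data were 11 substitute gene lists, the grouping of replicate numbers into 3 sets, the removal of a running median over 51 neighbouring feature numbers, and the named-gene rule applied also to the fit with the replicate number as a block. The substitute lists were composed from gene names on the array, after a table of the largest changes that held LHB1B2 and CSLA01 had been seen. They were tested with camera at a preset correlation of 0.01 against 612 genes, and with an estimated correlation and fry as alternatives. In all, 34 other settings of the count of changed features were run, 9 of them added after seeing the data. The running median is called the position trend here, though whether feature numbers follow the place on the array is not known.

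Deviations from the group means of same-numbered arrays correlated at 0.83, 0.84, 0.71, 0.7, 0.81 and 0.82 for numbers 1 to 6, across features, which are not independent replicates. Each of the 12 arrays correlated best with the array of its own number in the other group. The numbers were therefore taken as pairs, from the data and not from the labels, and values with the replicate number as a block stand beside results that it changes. Numbers 1 and 2, 3 and 4, and 5 and 6 also deviated together, with correlations from 0.4 to 0.81 within a group. Correlations with other sets lay below 0, which centring on the group mean brings about and which is no evidence for the sets.

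The fits were tested on simulated data for the 3091 features of the comparison of cytokinin with water. The 2-group fit recovered 11.9%, 62.7% and 92.4% of features changed by 0.25, 0.5 and 1 on the log2 scale, and the fit with the replicate number as a block 77.6%, 98.5% and 100%. Set means with the set as a block recovered 65.7%, 95.5% and 100%. That simulation kept the mean deviation of each replicate number, but its noise was independent. It lacked the correlation of the ratios of cytokinin to water within sets (0.62 to 0.72), so the recoveries with a block may be too high. Of the unchanged features, the 2-group fit called 0%, the replicate block 0.311% and set means with the set as a block 0.346%. For the replicate block, that share may be too low for the same reason.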

Results

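Transcript levels were measured on 12 arrays of Arabidopsis cell culture, 6 treated with water and 6 with cytokinin, as hybridization intensities with totals of 3743 to 3875 per array.

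The comparison asks which transcripts of the cell culture differed between 2 h of cytokinin, a plant hormone of cell division and greening, and water. LHB1B2, a light-harvesting chlorophyll a/b-binding protein of photosystem II, rose 1.61-fold with cytokinin, from a normalized intensity of 0.502 ± 0.0532 to 0.805 ± 0.0755 (SD, n = 6 arrays per group). AT1G35510, an O-fucosyltransferase family gene, rose 1.54-fold, from 3.86 ± 0.692 to 5.9 ± 0.544 (SD, n = 6). AT3G19120 fell by 0.53 on the log2 scale, from 1.78 ± 0.206 to 1.23 ± 0.117 (SD, n = 6). Each of these differences had the same sign in all 6 pairs of arrays with the same replicate number. The same held for all 48 features past the threshold without a block. The same arrays picked these features, which favours an equal sign in all pairs, so this agreement is no separate evidence.

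Of 3091 features tested, 34 rose and 14 fell at an adjusted p of 0.05 (limma), 48 in all. At least 1.5-fold change was reached by 3 of the rises and 3 of the falls. With the replicate number as a block, 200 features rose and 161 fell, and all 48 are among these 361. With the position trend removed as well, 226 rose and 252 fell, so rises were 47.3% of the calls and 55.4% before. The split of rises and falls depends on the scaling: 70.8% of the calls were rises after quantile normalization, 39.1% on the values as deposited and 82.4% after median scaling. The arrays of numbers 1 and 2, 3 and 4, and 5 and 6 deviated together (correlations from 0.4 to 0.81), so the independent samples may be fewer than 6 per group. With the arrays of a set averaged, 3 against 3, limma called 0 features without a block (99 at an unadjusted p of 0.05) and 41 with the set as a block, 24 of them among the 48. Without the arrays numbered 1 and 2, 5 features passed without a block and 160 with it.

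Among features with 1 gene name, 8 rose and 3 fell. After LHB1B2 (log2 change 0.68, SE 0.08, adjusted p = 0.00144) and AT1G35510 (0.63, SE 0.11, adjusted p = 0.0147), the rises were AT4G29890, annotated as choline monooxygenase-like (0.49, SE 0.06, adjusted p = 0.00144), AT2G28660 (0.48), CSLA01 (0.38), FZL (0.32), AT4G19900 (0.30) and AT3G52070 (0.29). CSLA01 belongs to the cellulose synthase-like A family of mannan synthases, FZL is a dynamin-related protein of thylakoid organization, and AT4G19900 is a glycosyltransferase-related gene. The falls were AT3G19120 (-0.53, SE 0.09, adjusted p = 0.011), AT5G63390 (-0.34, SE 0.07, adjusted p = 0.0245) and TCP15, a TCP-family transcription factor (-0.32, SE 0.07, adjusted p = 0.0487). With set means and the set as a block, FZL, AT4G19900, AT3G52070, AT5G63390 and TCP15 missed the threshold, with adjusted p between 0.0595 and 0.0908. Leaving out single arrays ended the call in 10 of 12 cases for AT4G19900 and AT3G52070, 7 for AT5G63390 and 11 for TCP15 (adjusted p up to 0.113), and in 0 of 12 for the other 7 genes. Without the arrays numbered 1 and 2, LHB1B2 and AT4G29890 passed (adjusted p = 0.0425 and 0.0143) and the other 9 genes did not (adjusted p from 0.0982 to 0.255). Of these 9, AT1G35510 still had a log2 change of 0.65 and AT3G19120 one of -0.45. With the replicate number as a block on the same arrays, 1 of the 11 genes missed the threshold. The other sets were not left out in turn, so these values do not single out numbers 1 and 2. With the position trend removed, AT3G52070 missed the threshold (adjusted p = 0.0798) at the same log2 change of 0.29. It passed with the replicate number as a block as well (adjusted p = 0.00419). Genes of the LHB1B2 family are close in sequence, and whether the feature separates them is not known here.

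**Figure D1:**
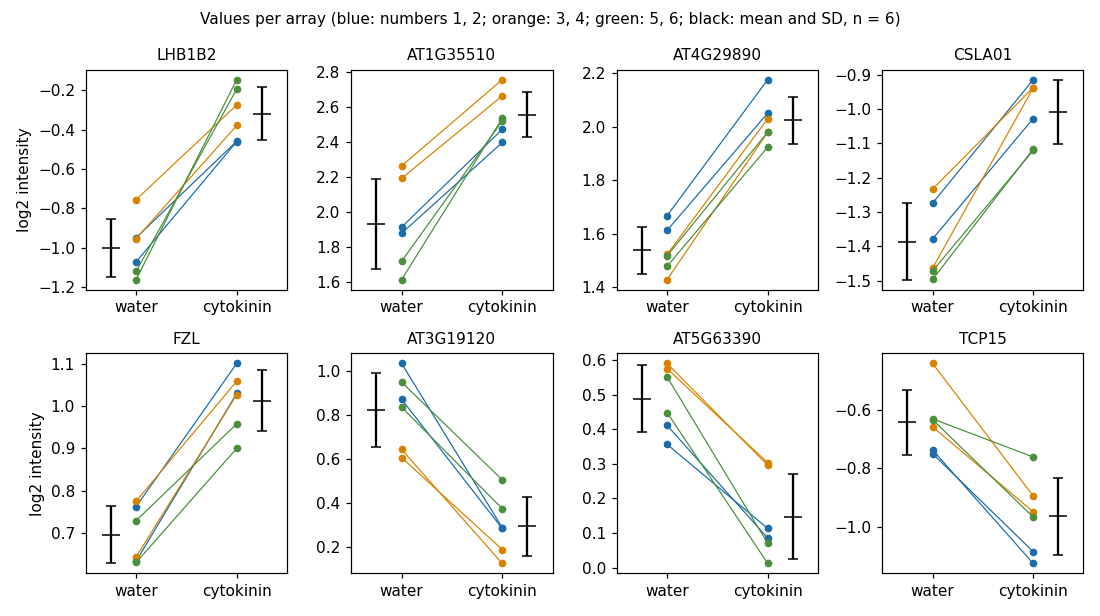
Log2 intensity of 8 named genes on each array, water at the left and cytokinin at the right of each panel, with lines joining arrays of the same replicate number, colours for the 3 sets of numbers, and the mean and SD (n = 6) in black; axes differ between panels. All 6 lines rise in the panels of LHB1B2, AT1G35510, AT4G29890, CSLA01 and FZL, and all 6 fall in those of AT3G19120, AT5G63390 and TCP15.

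The same rule applied to the fit with the replicate number as a block adds 13 genes that did not pass without it. With set means and the set as a block, 1 of the 13 passed, AT1G67930 (adjusted p = 0.0308), and the other 12 did not (adjusted p from 0.0772 to 0.194). PSAN, a photosystem I subunit, rose in that fit (log2 change 0.27, adjusted p = 0.0275 with the block, 0.792 without and 0.194 on the sets), as did AT3G54930, a regulatory subunit gene of protein phosphatase 2A (0.30), AT4G03150 (0.32) and AT1G01730 (0.31). NdhS, a subunit of the chloroplast NADH dehydrogenase-like complex, fell in it (-0.28, adjusted p = 0.032 with the block, 0.511 without and 0.181 on the sets). Z-ISO, the zeta-carotene isomerase of carotenoid synthesis, fell in it as well (-0.27, adjusted p = 0.00652 with the block, 0.0515 without and 0.107 on the sets). Features of NdhS, PSAN, AT5G02850, AT1G27610, AT4G33540 and AT3G19120 lie in 2 bins of feature numbers where the median ratio of numbers 1 and 2 was lower, and of these AT4G33540 missed the threshold with the block once that trend was removed (adjusted p = 0.0655). The other falls were AT1G67930 (-0.37), AT5G02850 (-0.37), AT4G20690 (-0.29), AT2G37580 (-0.28), AT1G27610 (-0.27), AT4G33540 (-0.26) and AT2G28790 (-0.24).

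Of 11 measured subunits and assembly factors of the photosystems, the NDH complex and the cytochrome complex, 1 rose (LHB1B2) and 0 fell, and with the replicate number as a block 2 rose (LHB1B2, PSAN) and 3 fell (NdhS, PSB27, LPA19). With set means and the set as a block LHB1B2 alone of these passed, and PSAN, NdhS, PSB27 and LPA19 did not (adjusted p from 0.142 to 0.194). PSB27 also missed the threshold with the replicate block once the position trend was removed (log2 change -0.23 before and -0.14 after, adjusted p = 0.113). The list as a whole did not pass camera (adjusted p = 0.575, and adjusted p = 0.603 with an estimated correlation). Of 5 cell wall glycosyl enzymes, CSLA01 rose and the others, all of glycosyl hydrolase family 9, did not pass (adjusted p of the list = 0.583). Of 22 organelle PPR and mTERF genes, 0 passed without a block; 18 had values below 0, with a median log2 change of -0.04 (adjusted p = 0.239, and adjusted p = 0.333 with an estimated correlation). Of 8 genes of S phase and mitosis, 7 had values above 0 and 0 passed (median 0.07, adjusted p = 0.575). Among the 6 genes of tetrapyrrole and pigment synthesis, 5 of plastid carbon metabolism, 5 fibrillins, 6 redox proteins, 3 organelle ribosomal proteins, 3 calmodulin-related genes and 6 of amino acid, sulfur and thiamine synthesis, 0 passed without a block. With the replicate number as a block, 1 fibrillin rose (AT5G19940, adjusted p = 0.0132), and Z-ISO, the peroxiredoxin gene AT3G52960 (0.0479), the PPR gene AT3G26630 (0.0371) and AT3G23940, the dihydroxyacid dehydratase of branched-chain amino acid synthesis (0.0244), fell. None of these 5 genes passed with set means and the set as a block (adjusted p from 0.107 to 0.297). In all, camera called 0 of the 11 lists, with 1 at an unadjusted p of 0.05, while fry, which does not compare a list with other genes, called 3: the PPR and mTERF genes (adjusted p = 0.0324), the photosystem list and the pigment list (0.0464 each). These lists were chosen after values had been seen, and LHB1B2 and CSLA01 were known when their lists were composed.

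Among features that do not have exactly 1 gene name, the 2 largest rises and falls past the threshold lay on unnamed features, singled out after their values were seen. Feature 1208 fell by 1.63 on the log2 scale (SE 0.13, adjusted p = 3.98e-05) and feature 923 fell by 0.75 (SE 0.14, adjusted p = 0.0167). Feature 1251 rose by 0.84 (SE 0.10, adjusted p = 0.00144) and feature 1994 by 0.52 (SE 0.08, adjusted p = 0.00772). Feature 1994 missed the threshold once the position trend was removed (log2 change 0.53, adjusted p = 0.17), but passed with the replicate block as well (adjusted p = 3.49e-05). In the fit without a block, features 1994 and 923 missed the threshold without the arrays numbered 1 and 2 (adjusted p = 0.124 and 0.0754). Their log2 changes were then 0.50 and -0.70. Of the 48 calls, 27 are on features without a gene name and 10 on features with several. The 2 features of AT2G25870 gave 0.05 and -0.16, neither past the threshold without a block and the second past it with one (adjusted p = 0.0372).

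**Figure D2:**
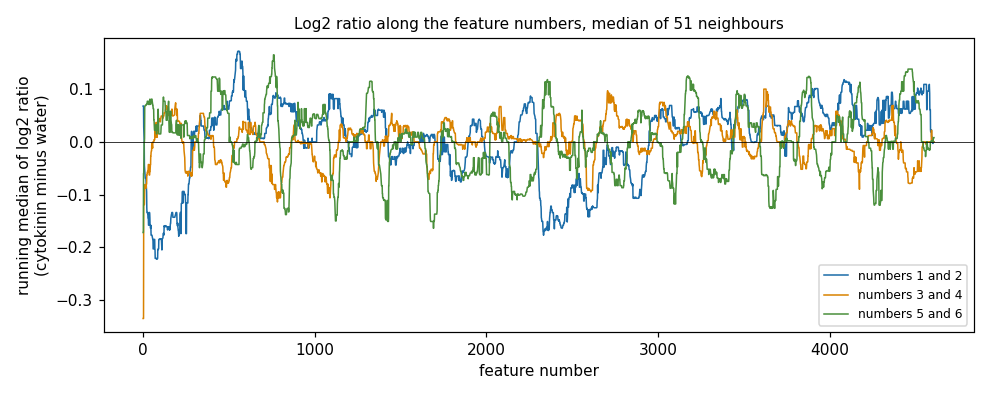
Running median over 51 neighbouring feature numbers of the log2 ratio of cytokinin to water (vertical axis) against the feature number (horizontal axis), 1 line for each set of replicate numbers. In the 2 of 24 equal bins of feature numbers that lay lowest in numbers 1 and 2, the median ratios of those numbers were -0.17 and -0.15, and elsewhere 0.017 and 0.015.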

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

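The sets, the position trend and the settings that use them were chosen after seeing the data, set as a block without averaging and set means without a block among them. The 48 changed features became 85 after median scaling, 76 with array weights and 6 with a 1.5-fold minimum. With the replicate number as a block the count was 361, with the position trend removed as well 478, and with the set as a block 310. Without the arrays numbered 1 and 2 it was 5, and 160 with the block. No other set was left out in this way. Set means without a block gave 0. Leaving out each array in turn gave 32 to 39. The other settings stayed within 1.5 times, but a like count can hold other features: the values as deposited gave 46, of which 29 are among the 48. Keeping the features at the floor on all arrays, as set beforehand, gave 63, with all 48 among them. Averaging the sets or leaving out arrays leaves fewer samples; elsewhere the cause was not tested. No named value turned its sign in any of 1076 values under other settings. That was to be looked for, since these features were picked for passing a threshold and the settings reuse the same arrays. Sizes did move: the log2 change of LHB1B2 ran from 0.399 to 0.742, that of CSLA01 from 0.185 to 0.407 and that of TCP15 from -0.425 to -0.179. LHB1B2 and AT4G29890 lost the threshold in 1 setting each, set means without a block, and TCP15 in 17 of 31. The count of gene lists, 0, became 3 with fry, which asks a different question, and the replicate block changed no list's call. The type-A response regulator mean and the fixed lists were not run, since none of their genes is the only gene of a feature; a filter on missing values did not apply. Features near the floor of 0.258 show changes as too small.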

Other observations

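The tests of position, apart from its effect on the pairing of arrays, were chosen after the results were seen. No array was flagged as far from the others of its group in 76 groups of 6 values, taken from 38 items. Of these items, 34 were named features, all picked for passing a threshold, which favours a small spread. The rate of about 1 in 20 from chance alone need not hold for them, and arrays that deviate together make a flag rarer. The absence of flags therefore says little about the arrays. The median intensity was lower in the cytokinin arrays (0.674 to 0.694) than in the water arrays (0.724 to 0.744), and the 34 brightest features held 21 to 21.7% of the total against 18.5 to 19.6%.

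The count of 48 changed features was set against other splits of the arrays. Of 100 splits drawn from 462, 4 gave as many, the real one included, and the highest other gave 702. The 3 other splits kept 2 sets whole and parted 0 to 2 pairs, which points to the structure of the samples. These splits treat the 12 arrays as exchangeable, which the pairs and sets contradict, so they cannot exclude a grouping by chance for these arrays. Among the 32 splits that part every pair, 1, the real one, gave 361 with the block, and the highest other gave 0; that count treats the 6 pairs as independent. With set means and the set as a block, 4 splits are too few for a share under 0.05 (real 41, highest other 0, 1 split as large). A trend along the feature numbers is argued against as the whole cause of the 48, since 36 stayed past the threshold once it was removed. A running median along feature numbers can miss other patterns of position, so position on the array as such is not excluded.

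Same-numbered arrays deviated together. A shared trend along the feature numbers is argued against as the whole cause, since the lowest correlation was 0.68 once it was removed, against 0.7 before. All 12 arrays correlated best with their own number. The arrays of a number may share a culture, an extract or a processing day, and these cannot be told apart, because the labels record none of them. The log2 ratios of LHB1B2 were 0.55, 0.53 and 0.97 in the 3 sets. Across features, the ratios correlated at 0.62 to 0.72 within sets and 0.25 to 0.34 between sets.

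With the replicate number as a block, 37 of the 161 falls (23%), NdhS and PSB27 among them, lay in the 2 of 24 equal bins of feature numbers whose median ratio was under -0.1 in both numbers 1 and 2, which hold 9.12% of the features tested. Ratios of numbers 1 and 2 chose the bins and also enter the calls. The excess of falls there may follow in part from that choice. The median ratio over both bins pooled was -0.17 and -0.15 in numbers 1 and 2. In numbers 3 to 6, which did not choose the bins, it was no farther from 0 than 0.043 (in single bins, no farther than 0.07). These values argue against a response shared by neighbouring features in all samples, but not against a response in numbers 1 and 2 only. Signal that varies with position may contribute: 81.1% of these falls stayed past the threshold once the trend was removed (exact 95% interval 64.8 to 92%), against 85.5% of the 124 falls elsewhere (two-sided Fisher's exact p = 0.605). The bins were first picked by eye, and a bound of -0.05, which takes in the bins so picked, gave 57 falls, of which 70.2% stayed (56.6 to 81.6%), against 92.3% of the 104 elsewhere (p = 0.000431 in the same exact test). The intervals and the exact tests count features as independent, though neighbours share the trend. The bins were also chosen for a low trend, so its removal tends to weaken falls inside them more than elsewhere. The comparison depends on the bound as well, so position and other causes cannot be told apart for these falls. PSB27 and AT4G33540 did not pass once the trend was removed (adjusted p = 0.113 and 0.0655), while NdhS did (0.0122).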
